A study of Mus musculus with 2 samples.

How the data were processed

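Trimethylation of histone H3 at lysine 36 (H3K36me3), a mark laid down over the bodies of transcribed genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in hearts of newborn mice on postnatal day 0. Per the labels, hearts were pooled from male and female mice of strain B6NTac;B6NCrl/Lap, and library fragments of 300 to 500 bp were selected. The series held 1 group of 2 biological replicates, each sequenced as 2 technical replicates. Replicate 1 was a pool of 15 mice and replicate 2 was a pool whose size the labels leave out. With 1 tissue, age and mark, the comparisons were between the replicates, between parts of the genome and between sets of genes.

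Peak lists were deposited in mm10 coordinates. Per the listings deposited beside them, each replicate's list was called on its own alignments with a control file of its own, a whole-series list was called on the alignments of both replicates with both control files, and a replicated list was derived from both replicate lists and the whole-series list. Each deposited peak carried a fold enrichment, a ratio of immunoprecipitate over control, in the column order of the narrowPeak format that the listings name. The deposited −log10 p and −log10 q of each peak were the authors' own, and every list started just above a −log10 p of 2. The aligner, the peak caller and its settings are not given in the sources used here. These scores were used to rank, filter or compare peaks within their own list. Fold enrichment was also correlated over peaks matched between the replicates, and its median was given for several lists. The lists gave no read counts, so sequencing depth was unknown for both replicates and no counting interval was computed. A region without a peak was therefore a region without detectable enrichment at this depth.

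Peaks on the 19 autosomes, X and Y were analysed, and peaks on sequences outside these assembled chromosomes were left out of every comparison. Chromosome lengths and assembly gaps came from the GRCm38 assembly, the same sequence as mm10, and the last peak on each chromosome ended within its length. Genes came from GENCODE release M21. A gene body ran from the first to the last base of all transcripts of a protein-coding gene; 27 records with a repeated symbol were left out, which left 21911 genes. The value of each gene was the percent of its body under peaks. Replicated peaks were the main list, and the value in each replicate's own list gave the spread as mean ± SD (n = 2). Values in the replicated list lay above the replicate means for most covered genes. The peaks of that list came from the alignments of both replicates and had a larger median width, but the cause was not tested. A gene of at least 1 kb was called marked when at least 10% of its body was covered. Comparisons within gene bodies used marked genes of at least 5 kb.

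Overlap between replicates was counted when at least 50% of the length of a peak was covered by the other list. It was compared with 100 placements of the other list's peaks at random within their chromosomes and outside gaps, in a one-sided permutation test whose smallest p is 0.0099. The share of peak bases in gene bodies, exons, introns, promoters (1 kb either side of a transcription start) and outside gene bodies was compared with 100 random placements in a two-sided permutation test whose smallest p is 0.0198. Differences within genes were tested by flipping the sign of each gene's difference at random 100000 times (two-sided, smallest p 1e-05). Each of 30 gene lists was compared with 100000 random lists of the same size matched on gene length in 20 bins (two-sided, smallest p 2e-05), with Benjamini-Hochberg adjustment over the 30 lists. Heart muscle genes were compared with genes of other tissues by permuting the class labels within 5 bins of length, and X with autosomes by permuting chromosome labels within 20 bins of length, each 100000 times. Genes of 1 genome are not independent replicates, so these p-values describe these lists of peaks and do not measure variation between mice. The list test was tried on simulated lists of 27 genes among 21196, with unadjusted p under 0.05. It called 3.5% of unchanged lists, 95% of lists raised by 10 percentage points and 100% of lists raised by 20. The simulated coverage left no gene uncovered, while 50.7% of the real genes had no replicated peak base, and real calls used adjusted p. These rates therefore do not give the sensitivity of the calls on the real lists.

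The main comparisons, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The comparisons under the heading Other observations were chosen after the main results were seen. Genes were named when they were among 33 fixed heart, other tissue and reference genes, among the 10 genes of at least 5 kb with the highest percent covered, the 2 highest or the lowest members of a list (ties to the longer gene), within the 5 longest domains, or among the 3 genes in each direction with the largest difference between replicates. Domains joined replicated peaks across gaps of up to 3 kb. Genes named outside this rule were chosen after their values were seen. They are the further X genes, the non-coding genes, the short heart genes without a peak, and the genes beside or around a named gene (Rnf5, Eif4a1, Epo, Arhgap23, Lims2 and Fyco1). Of the list members, Ahsp in the erythroid list and Whsc1, Whsc1l1 and Mrg15 in the H3K36 list, older names of genes the list also held, matched no symbol. Of the genes in the lists, 3 were members of several lists: Des, Hand2 and Kcnq1.

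Alternatives were each replicate's own list, the whole-series list, replicated peaks with −log10 q of at least 2 or fold enrichment of at least 3, gene bodies without bases shared with another protein-coding gene, no minimum gene length, and marking at 5% or 20%. Further alternatives were overlap by 1 bp or by 50% of both peaks, the 50000 strongest peaks of each replicate, −log10 p in place of fold, random lists not matched on length, the share of marked members in place of mean coverage, and heart muscle without the transcription factors. For the closing observations, repeats were the lower-case bases of the assembly, GC content came from the same sequence, and the families left out of the X comparison were predicted or unnamed genes (Gm and Rik symbols) and families such as Mage, Rhox, Xlr, olfactory receptors and keratins, from X and autosomes alike. Computations used python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Overlap by 50% of both peaks, and overlap of the replicated and whole-series lists with the replicates' own lists, was counted with bedtools 2.31.1.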

Results

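H3K36me3 was mapped in newborn mouse heart as peak lists of 2 biological replicates, each a pool of hearts from both sexes on postnatal day 0. Replicate 1 had 189432 peaks over 98.4 Mb (3.72% of the genome) and replicate 2 had 197560 peaks over 100.1 Mb (3.78%). The list called on both replicates together had 193847 peaks over 143.4 Mb, and the replicated list had 105738 peaks over 116.7 Mb (4.41% of the genome). Median peak width was 353 bp in replicate 1, 340 bp in replicate 2 and 726 bp in the replicated list. The authors' median fold enrichment was 3.43, 3.40 and 3.75 in these lists. Read depth was unknown. All coordinates are mm10 (GRCm38).

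The first comparison was between the replicates. Of replicate 1 peaks, 56.7% were covered over at least 50% of their length by replicate 2 peaks, against 3.70% for randomly placed peaks. Of replicate 2 peaks, 55.4% were covered by replicate 1, against 3.69% at random. Bases in both lists made up 46.3% of the bases in either, against 2.14% at random. Each of these 3 values exceeded all 100 random placements (one-sided permutation p = 0.0099, the smallest possible). The placements took no account of genes, whose bodies held 95.9% of replicated peak bases. Lists that share only this preference for genes could also exceed them, so p does not measure how closely the replicates agree. The overlap fell with peak strength, from 93.3% in the strongest 10% of replicate 1 peaks to 33.9% in the weakest 10%, and from 91.5% to 32.2% in replicate 2. Shared peaks had a higher median fold enrichment than peaks of 1 replicate alone, 3.83 against 3.14 in replicate 1 and 3.71 against 3.14 in replicate 2. Over 60980 pairs of peaks that covered each other by at least 50%, fold enrichment correlated between replicates with Pearson's r of 0.417 and Spearman's rho of 0.374 across peaks, which are not independent replicates.

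**Figure D1:**
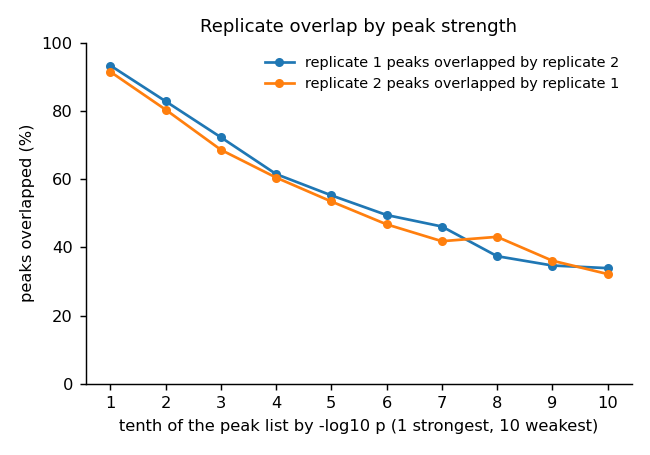
Percent of peaks of each replicate (vertical axis) overlapped over at least 50% of their length by the other replicate, in 10 equal parts of the list ranked on −log10 p (horizontal axis, 1 strongest to 10 weakest). Overlap falls from 93.3% to 33.9% in replicate 1 and from 91.5% to 32.2% in replicate 2.

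The replicated list was a subset of the whole-series list and held 54.5% of its peaks, with identical positions and scores. On the assembled chromosomes, 90801 of its 105732 peaks (85.9%) overlapped a peak of both replicates by 50% of either peak, and none of the 88102 whole-series peaks left out of it did. The remaining 14931 replicated peaks had a median fold enrichment of 3.12, against 3.89 for those found in both replicates. Of these, 7354 overlapped replicate 1 alone, 7187 overlapped replicate 2 alone and 390 overlapped neither. With only the 90801 peaks found in both replicates, 7918 genes passed the marking threshold, against 8220 with all replicated peaks. The share found in both replicates fell to 35.9% when 50% of both peaks was required.

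Peaks lay within genes. Protein-coding gene bodies held 95.9% of replicated peak bases and make up 39.2% of the genome. Exons held 23.8% of peak bases, 6.58-fold their share of the genome, and introns held 72.1%, 2.02-fold their share. Promoters, within 1 kb of a transcription start, held 0.294% of peak bases against 1.56% of the genome. Each share lay outside the range of 100 random placements (two-sided permutation p = 0.0198 each, the smallest possible), and gene bodies held 95.7% and 95.8% of peak bases in the lists of replicates 1 and 2.

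Joining peaks across gaps of up to 3 kb gave 21188 domains, of which 326 were at least 50 kb long. The longest spanned 253 kb of chromosome 2 (76702184 to 76955322) over most of Ttn, which encodes the giant sarcomere protein titin, and past its 3′ end, and 85.6% of it was under replicated peaks. A domain of 156 kb on chromosome 4 (145035145 to 145191198) lay in Vps13d, and one of 129 kb on chromosome 5 (101832448 to 101961544) lay over part of Wdfy3. A domain of 130 kb on chromosome 5 (121253791 to 121383513) covered parts of Hectd4 and Trafd1, and one of 122 kb on chromosome 5 (32865976 to 32988175) lay in Depdc5. Peaks covered between 48.1% and 78.0% of each of these 5 domains in each replicate's own list.

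Of 21196 protein-coding genes of at least 1 kb, 8220 (38.8%) were marked over at least 10% of their body. In the replicates' own lists 7929 and 7985 genes were marked, 7538 of them in both. Of the 8220 genes, 7515 were marked in both replicates' own lists and 161 in neither. No replicated peak base fell in 10738 genes (50.7%). Coverage of single genes below, 0% included, is that of the replicated list unless another list is named. Marked genes had a median coverage of 39.6% and a median length of 22.8 kb, against a median length of 15.2 kb for the others. Percent covered correlated between replicates with Pearson's r of 0.971 and Spearman's rho of 0.962 across genes, which are not independent replicates.

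The 10 most covered genes of at least 5 kb were Gigyf1 (97.0%), 1700109H08Rik (94.4%), Sf3a1 (93.6%), 4933428G20Rik (93.3%), Kpnb1 (93.0%), Trrap (93.0%), Rnf40 (92.0%), Glyr1 (91.0%), Ddb1 (90.9%) and Gpi1 (90.8%). Several serve functions common to most cells: Sf3a1 encodes a splicing factor, Kpnb1 importin beta, Trrap a scaffold of histone acetyltransferase complexes and Ddb1 a ubiquitin ligase adaptor. In the replicates' own lists their mean coverage ran from 65.6 ± 15.0% (SD, n = 2) for 4933428G20Rik to 85.7 ± 3.34% (n = 2) for Ddb1. The annotated bodies of Gigyf1 and 4933428G20Rik lie entirely inside those of other coding genes, Epo and Arhgap23, so their peaks cannot be assigned to 1 gene.

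Coverage rose along the gene body. In 7544 marked genes of at least 5 kb, mean coverage was 1.73% in bin 1 of 20 equal bins, 45.9% in bin 10 and 63.2% in bin 18, and 55.6% in bin 20 at the 3′ end. The 3′ 50% of the body was covered over 56.9% and the 5′ 50% over 26.8%, a difference of 30.2 percentage points that was positive in 88.0% of genes. The difference was 25.0 points in replicate 1 and 25.7 points in replicate 2. The sign-flip permutation test over genes gave p = 1e-05 (two-sided), the smallest possible, with genes not being independent replicates.

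**Figure D2:**
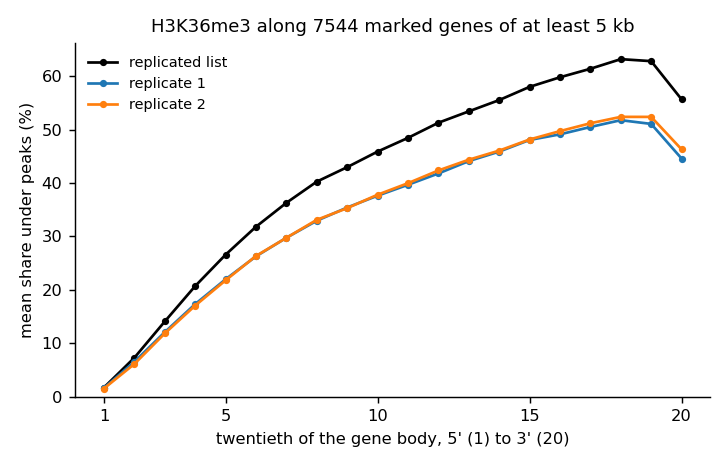
Mean percent of each of 20 equal bins of the gene body under peaks (vertical axis), from the 5′ end (bin 1) to the 3′ end (bin 20, horizontal axis), over 7544 marked genes of at least 5 kb, for the replicated list and each replicate's own list. In the replicated list the mean rises from 1.73% in bin 1 to 63.2% in bin 18, and the lines of both replicates lie close to each other.

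Peaks also ran past the ends of genes. Among 923 marked genes with no other gene within 10 kb, the 5 kb downstream of the gene end were covered over 14.6% and the 5 kb upstream of the start over 0.062%. The difference of 14.5 percentage points was positive in 60.8% of these genes and negative in 0.108% (sign-flip permutation p = 1e-05, two-sided, the smallest possible). It was 12.7 points in replicate 1 and 12.1 points in replicate 2.

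Within the same genes, exons were more covered than introns. In 7532 marked genes of at least 5 kb, the mean over genes was 57.2% of exon bases and 38.3% of intron bases under peaks. The mean difference was 18.8 percentage points, positive in 79.8% of genes. The difference was 16.2 points in replicate 1 and 16.7 points in replicate 2 (sign-flip permutation p = 1e-05 over genes, two-sided, the smallest possible).

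Heart muscle genes were compared with genes typical of other tissues. The 85 genes of the sarcomere, cardiac transcription factor and calcium handling lists were covered over 25.8% of their bodies on average, against 0.510% for 191 genes of liver, brain, skeletal muscle, gut and pancreas, lung and kidney, skin and germ cells. Des, in both the sarcomere and the skeletal muscle list, was left out of both sides. The difference of 25.3 percentage points was 20.5 and 20.4 points in the lists of replicates 1 and 2 (two-sided permutation within length bins, p = 2e-05, the smallest possible).

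Sarcomere genes carried long stretches of the mark. Myh6, the alpha myosin heavy chain (chromosome 14, 54941921 to 54966927), was covered over 83.4% of its body, with 62.3 ± 1.65% (SD, n = 2) in the replicates' own lists. Myh7, the beta heavy chain that lies beside it (chromosome 14, 54970684 to 54994626), was covered over 66.6% (48.6 ± 1.09%, n = 2). Mybpc3, cardiac myosin binding protein C, reached 84.1% (66.4 ± 1.94%, n = 2), Ttn 81.8% (72.4 ± 2.88%, n = 2) and Tnnt2, cardiac troponin T, 74.3% (57.8 ± 1.33%, n = 2). Actc1, cardiac alpha actin, was covered over 55.2% (36.6 ± 2.74%, n = 2). Tnni3, the cardiac isoform of troponin I, was covered over 34.1% (30.3 ± 0.764%, n = 2) and Tnni1, the slow skeletal isoform that fetal heart also expresses, over 15.2% (11.6 ± 0.303%, n = 2). Xirp2 had no replicated peak.

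**Figure D3:**
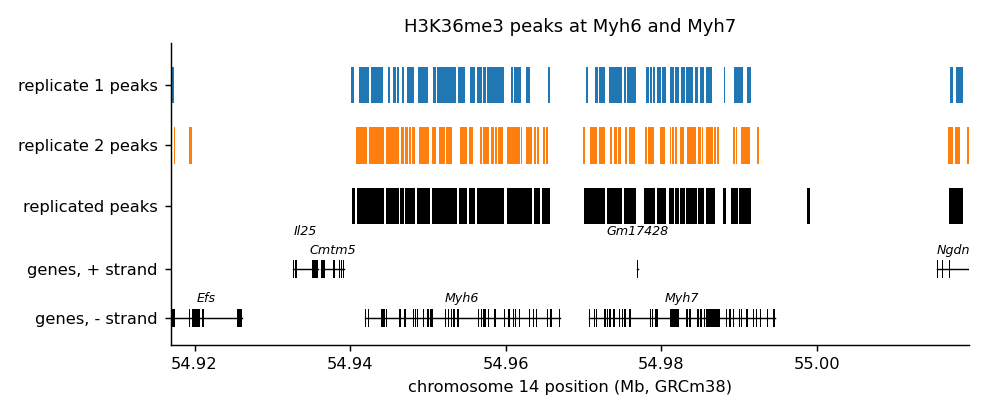
Peaks of replicate 1, replicate 2 and the replicated list (coloured blocks) over Myh6 and Myh7 on chromosome 14, with protein-coding genes of each strand below (thick blocks are exons); the horizontal axis is the position in Mb. Replicated peaks cover 83.4% of Myh6 and 66.6% of Myh7.

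Among calcium handling genes, Atp2a2, the calcium pump of the sarcoplasmic reticulum, was covered over 83.4% (77.4 ± 2.34%, n = 2), and Atp1a1, a sodium pump subunit, over 67.4% (65.5 ± 1.62%, n = 2). Ryr2, the calcium release channel, was covered over 33.4% of its 554 kb (26.9 ± 0.389%, n = 2) and Slc8a1, the sodium-calcium exchanger, over 12.8% of its 365 kb (12.4 ± 0.341%, n = 2). Kcnd2, a potassium channel gene, had no peak in any of the 3 lists. Of the transcription factors, Gata6 was covered over 79.3% (64.9 ± 0.0632%, n = 2), Tbx20 over 52.8% (44.5 ± 0.0818%, n = 2), Tbx5 over 29.1% (24.4 ± 4.53%, n = 2), Nkx2-5 over 15.8% (12.7 ± 4.04%, n = 2), Gata4 over 13.9% (13.9 ± 2.93%, n = 2) and Mef2c over 10.2% (9.67 ± 1.27%, n = 2). Hand2 was covered over 11.6%, with 7.48% in replicate 1 and 0% in replicate 2, and Irx5 had no peak. Nppa and Nppb, which encode natriuretic peptides abundant in heart and span 1.36 kb and 1.42 kb, had no peak in any of the 3 lists.

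Of the 30 gene lists, 10 were more covered than random lists matched on gene length and 12 were less covered (Benjamini-Hochberg adjusted permutation p under 0.05). The cardiomyocyte sarcomere list was covered over 41.4% against 15.8% for random lists, with 25 of 30 genes marked (32.2 ± 0.00157%, SD, n = 2 replicates). Lists of energy metabolism also lay above random lists. Oxidative phosphorylation was covered over 56.1% (29 of 30 marked), led by the complex I genes Ndufa10 (87.1%) and Ndufa9 (84.1%), and Cox7a1 had no replicated peak but 20.4% in the whole-series list. Fatty acid oxidation was covered over 47.5% (24 of 25 marked), with Acadvl at 79.0%, Hadha at 77.6% and Ppara, a transcription factor of lipid metabolism, at 6.25%. Of the Acadvl body, 40.5% is shared with another coding gene. Glycolysis was covered over 43.9% (19 of 20 marked), with Gpi1 at 90.8%, Ldhb at 73.0% and no replicated peak in Aldoc. The adjusted permutation p was 3.53e-05 for each of these 4 lists.

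Lists of functions that most cells share also lay above random lists, as did the H3K36 list and the genes named Zfp. Cell cycle genes averaged 59.0% (30 of 32 marked), with Rrm1 at 78.8%, Mcm3 at 78.7% and Ccnd3 at 1.52%. This list differed between the replicates, at 49.8% in replicate 1 and 44.2% in replicate 2. Proteasome genes averaged 58.0% (28 of 29 marked, Psmc4 at 87.4%, Psmc1 at 81.6% and Psmd14 at 7.30%). Splicing factors averaged 57.3% (35 of 36 marked, Sf3a1 at 93.6%, Sf3a3 at 89.3% and Mbnl1 at 6.00%). Cytoplasmic ribosomal proteins averaged 51.4% (32 of 33 marked, Rps5 at 79.4%, Rpl5 at 78.2% and Rps14 at 7.02%). Writers, erasers and readers of H3K36 methylation averaged 44.5% (21 of 24 marked), with the reader Glyr1 at 91.0%, the demethylase Kdm4a at 88.5% and Phf19 at 1.66% (5.19 ± 3.48% in the replicates' own lists, n = 2). Setd2, the enzyme that trimethylates H3K36, was covered over 52.3% (45.1 ± 2.69%, n = 2). The 394 genes named Zfp averaged 26.0% against 20.1% for random lists, with 259 marked, from Zfp869 at 100% and Zfp335 at 87.6% to Zfp804b at 0%. All 6 lists had an adjusted permutation p of 3.53e-05. Among reference genes, Actb was covered over 60.5% (53.5 ± 7.58%, n = 2) and Gapdh over 29.6% (24.6 ± 6.62%, n = 2).

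None of 39 Hox genes, 1069 olfactory receptor genes and 275 vomeronasal receptor genes had a peak base in either replicate or in the replicated list. Their random lists averaged 12.2%, 13.9% and 19.2%, and Hoxc5, Hoxa3, Olfr56, Olfr643, Vmn2r7 and Vmn2r60 are their longest members. Lists of other tissues had almost none. The liver list averaged 0.00323% (Hnf1a 0.0904%, and Cps1 and Alb 0%), pancreas and intestine 0.0721% (Vil1 1.95%, Lgr5 0%), skin 0.156% (Col17a1 3.74%, Trp63 0%), brain neurons 0.225% (Dlg4 4.54%, Camk2a 2.47%, and Cntnap2 and Neurod1 0%) and germ cells 0.458% (Mov10l1 11.9%, with 8.63% in replicate 1 and 13.5% in replicate 2, and Tex11 0%). Lung and kidney averaged 1.48%, with Ager at 27.9%, Slc5a2 at 7.85% (12.8% in replicate 1, 7.74% in replicate 2 and 16.6% in the whole-series list) and Cubn at 0%, and skeletal muscle 3.24%. In the skeletal muscle list Des (61.8%; 39.8 ± 6.32%, n = 2), which heart and smooth muscle also express, and Atp2a1 (14.7%; 11.5% in replicate 1 and 4.29% in replicate 2) led, while Ryr1 and Myod1 had no peak. Ager lies 154 bp from Rnf5, which was covered over 24.2%, and 19.6% of the Atp2a1 body is shared with another coding gene. Without shared bases Atp2a1 and Slc5a2 were at 0%. Adjusted permutation p for these 10 lists was between 3.53e-05 and 0.0002.

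Markers of the other cells of the heart were unevenly covered. The peak lists came from heart tissue as a mixture of cells, so these values do not measure the mark within single cell types. The epicardial list averaged 0.941% (Tbx18 10.1%, Wt1 2.10%, Sema3d 0%; adjusted permutation p = 0.00166) and glia and peripheral neurons 1.20% (Erbb3 12.5%, and Sox10 and Mbp 0%; adjusted permutation p = 0.0002), both below random lists. Leukocyte genes averaged 6.05% (3 of 24 marked, adjusted permutation p = 0.0642), with Ptprc and Adgre1 at 0% and Cx3cr1 at 23.8%. The highest value in that list was 99.2% in Cd68, a gene of 1.94 kb that lies 782 bp from Eif4a1, a translation factor gene covered over 63.1%. More than 50% of the annotated Cx3cr1 body (53.2%) is shared with another coding gene, and without those bases its coverage was 1.66%. Erythroid genes averaged 6.33% (4 of 16 marked, adjusted permutation p = 0.0627), with the transferrin receptor Tfrc at 61.8%, Sptb at 13.8%, and Rhag and the globin gene Hbb-bs at 0%. Without a minimum gene length this list held 18 genes. Hbb-bs spans 1.56 kb, and 791 of 869 genes of 1 to 2 kb had no replicated peak.

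Fibroblast genes averaged 12.2% (7 of 26 marked, adjusted permutation p = 0.229), with Fn1 at 65.6%, Vim at 62.7%, Postn at 8.66% and no replicated peak in Ddr2. Col1a1 had no replicated peak either, though peaks of the replicates' own lists covered 4.48 ± 4.27% (n = 2) of it. In the whole-series list Col1a1 was at 18.8% and Postn at 15.3%, above the marking threshold. Endothelial genes averaged 10.3% (7 of 24 marked, adjusted permutation p = 0.262), with Nrp1 at 55.9%, Eng at 37.9%, Cdh5 at 8.17%, Pecam1 at 6.45% and Emcn at 0%. Cdh5 and Pecam1 passed the marking threshold in the whole-series list, at 20.9% and 14.3%, and Cdh5 also in both replicates' own lists, at 11.2% and 10.1%. Smooth muscle and pericyte genes averaged 21.4% (7 of 18 marked, adjusted permutation p = 0.385), with Mcam at 70.5%, Smtn at 63.7%, and Myh11 and Itga8 at 0%. Cardiac transcription factors averaged 18.0% (17 of 28 marked, adjusted permutation p = 0.4) and ion channel and calcium handling genes 18.0% (14 of 28 marked, adjusted permutation p = 0.0861). Imprinted genes averaged 11.4% (11 of 34 marked, adjusted permutation p = 0.301), with Igf2r at 67.0%, Cd81 at 56.5% and Usp29 at 0%. None of these 8 lists, from leukocyte to imprinted genes, passed the threshold. When the share of marked genes replaced mean coverage, the transcription factors and the ion channel list lay above random lists (adjusted permutation p = 0.0128 and 0.0324) and the leukocyte list below (0.0324). The leukocyte list also passed without replicate 1 (adjusted permutation p = 0.0491), in the whole-series list (0.0205), without bases shared between genes (0.0408) and without length matching (0.0192), and the ion channel list passed in the whole-series list (0.0458).

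**Figure D4:**
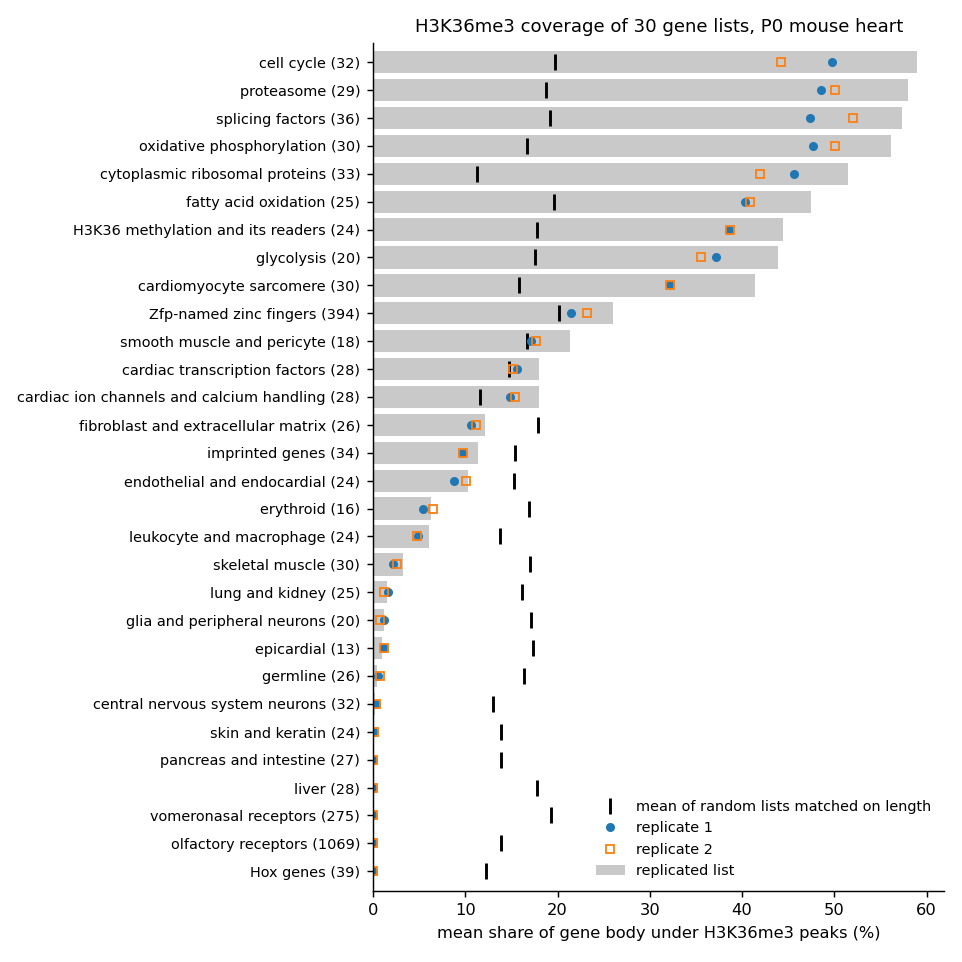
Mean percent of gene body under peaks (horizontal axis) for 30 gene lists, with the number of genes in brackets; bars are the replicated list, circles and squares the replicates' own lists and black ticks the mean of random lists matched on gene length. Cell cycle genes average 59.0% and sarcomere genes 41.4%, while Hox, olfactory and vomeronasal receptor genes are at 0%.

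Genes on the X chromosome were marked less often than autosomal genes. On X, 114 of 877 genes (13.0%) were marked, against 40.2% of 20156 autosomal genes and 36.3% expected for genes of the same lengths. The difference between X and autosomes was −27.2 percentage points in the replicated list, −25.4 in replicate 1 and −25.8 in replicate 2 (two-sided permutation p = 2e-05, the smallest possible). Single autosomes ranged from 31.3% on chromosome 14 to 48.7% on chromosome 8, and none of 163 genes on Y was marked. Further examples of marked X genes, chosen after their values were seen, were the chromatin regulator Kdm5c at 58.5% (49.5 ± 8.91%, n = 2), the RNA helicase Ddx3x at 49.5% (43.5 ± 4.96%, n = 2) and Ogt at 44.7% (36.9 ± 2.41%, n = 2). Replicated peaks on X had a median fold enrichment of 3.46, against 3.75 on autosomes.

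Single genes differed between the replicates. Among genes of at least 5 kb, the largest differences toward replicate 1 were in Coro1b (59.0% against 20.0%), Cdkn2aipnl (54.4% against 20.0%) and Cdk1 (76.1% against 43.9%), the kinase that drives entry into mitosis. Toward replicate 2 they were in Gpr17 (0% against 38.9%), Npm1 (37.7% against 68.0%) and Cxcr6 (37.5% against 67.7%). The annotated bodies of Gpr17 and Cxcr6 lie entirely inside those of Lims2 and Fyco1. The median absolute difference between the replicates over the 8220 marked genes was 3.80 percentage points.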

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

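Replicate 1 had 13 peaks and replicate 2 had 14 peaks on sequences assigned to chromosome 4 or X but without a position in the assembled chromosomes, which no comparison used; they stand out because any such peak is signal in data left aside. In each replicate 7 of these peaks lay on a sequence assigned to X.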

How the results depend on the processing

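Every alternative was fixed before the data were examined. Of 122 alternatives to the 20 values of the comparisons, 118 kept their direction and their side of the threshold, or stayed within the replicate spread or within 1.5 times the count. Of the 118, 3 could not change in value by construction (the overlap rule for shared bases, and shared gene bases for isolated genes). A further 15 used a −log10 q filter that keeps 99.5% of replicated peaks. Without these, 100 of 104 did. The 100 still count the peak strength difference of each single replicate. That value always lies within the SD of the replicates around their mean, so it was no check. The 104 still include values that follow from others: the shares outside gene bodies and outside any annotated gene mirror the shares inside. The intron share is that of gene bodies less that of exons. The share of replicated peaks found in both replicates was 86.5% with an overlap of 1 bp and 35.9% with 50% of both peaks, which fewer peaks meet by construction. The difference in median strength between shared and single peaks, 0.633 on average in fold enrichment, was 0.546 with an overlap of 1 bp and 2.08 when −log10 p, another scale, replaced it; it was 0.573 to 0.692 in single replicates. Leaving out a replicate in turn gave 7929 to 7985 marked genes, a rise toward the 3′ end of 25.0 to 25.7 percentage points, an exon excess of 16.2 to 16.7 points, a downstream excess of 12.1 to 12.7 points, a heart muscle excess of 20.4 to 20.5 points and an X difference of −25.8 to −25.4 points. The count of marked genes ran from 6661 (marking at 20%) to 9174 (whole-series list). Lists above random lists numbered 10 to 12 and lists below 12 to 13 over the settings.

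Of 270 alternatives for single lists, 261 were like the value reported. Leukocyte genes passed the threshold in 5 settings (adjusted permutation p 0.0192 to 0.0491), ion channel genes in 2 (0.0324 and 0.0458) and cardiac transcription factors in 1 (0.0128). The smooth muscle list reversed, uncalled both times, with 38.9% of genes marked; the cause was not tested. Among 738 values of 124 named genes, 237 moved by more than the replicate SD. The whole-series list gave higher coverage for 67 of these genes and equal coverage for 57. Of 54 named genes under 10%, 10 reached 10% in the whole-series list. Read depth was unknown, so genes without a peak may hold enrichment below detection.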

Other observations

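All tests and comparisons in this section, and the patterns they weigh, were chosen after the main results were seen. Away from coding genes the mark was rare on long non-coding RNA genes. Of 4537 such genes of at least 1 kb lying more than 5 kb from any protein-coding gene, 26 (0.573%) were marked. Among those marked, named after their values were seen, Malat1, an abundant nuclear RNA, was covered over 74.2% (59.0 ± 0.759%, SD, n = 2), Snhg17 over 74.8% (66.5 ± 4.74%, n = 2) and Mir17hg, the host of a cluster of microRNAs, over 69.2% (49.7% in replicate 1 and 66.7% in replicate 2). Lncppara, near Ppara on chromosome 15, was covered over 47.3% of its 53.9 kb (38.4 ± 2.64%, n = 2), while Ppara itself was at 6.25%.

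Marking varied with gene length, and short heart genes were among the uncovered ones. Of all genes of 1 to 2 kb, 7.94% were marked, against 23.8% at 2 to 5 kb, 49.6% at 10 to 50 kb and 25.1% above 100 kb. Members of the ubiquitous lists were marked in 1 of 2 cases at 1 to 2 kb, in 36 of 37 at 2 to 5 kb and in 41 of 41 at 5 to 10 kb. Among all genes, 791 of 869 at 1 to 2 kb and 1885 of 2548 at 2 to 5 kb had no replicated peak. Of 7 heart muscle genes under 5 kb, 5 had no replicated peak either, as was common for genes of these lengths. They were Tcap, Myl7, Sln, Hand1 and Irx3, named after their values were seen. No explanation for this was tested.

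The first pattern weighed is the low share of marked genes on X. Fewer reads on X are argued against as the whole cause: in the whole-series list, called on both replicates' reads, 19.3% of X genes were marked, against a length-matched expectation of 35.0% and 35.2% in the replicates alone. Gene families and unnamed genes are argued against too, since without them 17.4% of 619 X genes were marked against 43.8% expected (permutation p = 2e-05, the smallest possible). Lower enrichment from a single active X copy cannot be told apart from other causes: median fold of X peaks was 0.923 of the autosomal one, but peaks below the calling threshold are missing from both, and marked X genes had a median coverage of 22.3% against 39.9% on autosomes, which goes with weaker signal on X. A different makeup of X in genes used by heart may also contribute and was not tested.

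The second pattern is the higher coverage of exons than of introns. Position in the 5′ or the 3′ 50% of the body is argued against as the whole cause. Within the 3′ 50% the difference was 12.4 percentage points over 7430 genes (67.1% against 54.7%), against 18.8 points over the whole body. Coverage still rose inside the 3′ 50%, from 48.4% in bin 11 to 63.2% in bin 18. Exons and introns were not matched on position there, so finer position stays open. Repeats are argued against as well, with a difference of 17.5 points over bases not masked as repeats. In unmasked windows of 200 bp in the 3′ 50%, the difference was 16.4 points over 4912 genes both before and after adjustment for GC content within genes. Exons were above introns in 16 of 18 GC bins with at least 200 exon windows, so base composition alone does not account for the difference. Its size varied with GC content, from −2.25 points at 30 to 32% GC to 15.2 points at 48 to 50% and 42.1 points at 64 to 66%. The sign-flip permutation p was 1e-05 for the differences of 12.4, 17.5 and 16.4 points, the smallest possible. A link of the mark to exons is a candidate explanation that the design, with 1 group, did not test.

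The third pattern is the higher coverage of cell cycle genes in replicate 1, 49.8% against 44.2% and higher in 23 of 32 genes. Gene-to-gene noise is argued against by an adjusted permutation p of 0.00128 over 16 lists, against random lists matched on mean coverage, and base composition and gene length by the 100.8% of the difference left after their trend was removed. In the same test, over genes covered in at least 1 replicate (319 of the 394 Zfp genes), ribosomal protein genes were higher in replicate 1 (45.6% against 42.0%, adjusted permutation p = 0.0258), and splicing factors (47.4% against 52.0%, 0.00235) and Zfp genes (26.5% against 28.6%, 0.00032) higher in replicate 2. Without the GC and length trend the splicing and Zfp lists kept their calls (adjusted permutation p = 0.0133 and 0.00064), while the ribosomal difference went from 3.65 ± 1.63 to 2.90 ± 1.63 points (SE over 33 genes) and lost its call on adjustment over the lists (permutation p = 0.0213, adjusted 0.085), which does not show that the trend explains it. The pools may differ in their cells or their handling, which 1 peak list per pool leaves open, and no biological explanation was tested.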
